A study of Callithrix jacchus with 4 samples.

How the data were processed

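Each of the 4 samples is 1 array on which the nigral RNA of 1 MPTP animal was set against that of the vehicle animal. Per the labels' protocols, RNA of laser-captured tissue was purified, amplified in 2 rounds and labelled with Cy3 (vehicle) or Cy5 (MPTP). It was hybridised to a whole-genome oligonucleotide array designed for human transcripts, so marmoset RNA was read by human probes. The labels name 1 vehicle animal and 1 MPTP animal for each time, and no dye swap.

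The deposited table held 1 value per feature and array, read here as log10 ratios of Cy5 over Cy3. This reading rests on the form of the values: column medians were 0.00633, 0.000146, 0.000277 and 0, no value passed 2 in size and each array reached exactly 2, and 4.70% to 7.38% were exact zeros. The software, the background correction and the normalization used by the authors are not given in the sources used here. Scale and direction of the ratio stay inferred. The table held no spot intensities, so signal over background is unknown and no filter on dim features was possible. The number of arrays, 1 per time, limits the precision.

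Values were multiplied by log2 of 10, each array was centred on the median over all features, and a gene's value was the median over its features. Gene symbols came from the platform annotation given with the data. Of 43931 features, 29033 (66.1%) had 1 symbol, 97 had several and were not used for genes, and 14801 were unnamed. These gave 18014 genes, 10603 (58.9%) of them with 1 feature. Of the symbols, 15319 (85.0%) occur in the marmoset RefSeq gene table (assembly calJac240_pri), which was used only for names and gene order. The annotation gives features and not probe sequences, so the planned requirement of different probes was applied as 2 or more features, some of which may be repeat spots.

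Without replicates no test across genes was run. A gene was counted as higher or lower at 2-fold, a log2 ratio of 1. Genes on all 4 arrays, correlations and overlaps were set beside 100 simulations of unchanged samples against 1 shared control and beside independent lists. The simulations drew each MPTP sample from its own array and the control from the values of all 4 arrays together. The control's share of the variance therefore differed between arrays, and the data do not settle it. Simulated arrays were wider than the real ones at 1 day and 14 days and narrower at 2 h. For genes with 2 or more features, the number whose features all passed was set beside 1000 shuffles of the features. Each of 29 gene lists was described by its median, by a 95% bootstrap interval over members (2000 resamples) and by its percentile among 10000 random lists of the same size, matched on the number of features per gene. A list stood apart outside the central 99%. The percentile describes these arrays and not the condition. Of 585 list members 542 were measured, and the other 43 were not analysed here. The gene lists, the 2-fold threshold, the rule for named genes and the alternatives listed first below were chosen before the data were examined.

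The rule for named genes took, at each time, the 8 highest and 8 lowest genes among those with 2 or more features all at least 2-fold in 1 direction, and the 4 highest and 4 lowest of all genes. Over time it took the 8 genes with the largest smallest difference among those higher on all 4 arrays, 8 among those lower, and the 8 early and 8 late genes with the largest difference. From each list it took up to 4 members with the largest difference among those at least 2-fold from vehicle at that time. A set of 12 genes of dopamine neurons, glia and stress was always included, of which 10 were measured. The text names fewer than the rule allows, and genes known only by a clone or open reading frame name are not named.

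The alternatives were values without centring, the mean over features, a 3-fold threshold, arrays scaled to 1 median absolute deviation, only genes with 2 or more features that all passed, only genes with every value present, and random lists without matching. Alternatives added after seeing the data were exact zeros taken as not measured, centring on named features, each array left out of the counts over 4 arrays, and subtraction of a regional median. For the last, the median of the genes 10 to 30 places away on either side in the marmoset gene order, at least 20 of them, was subtracted from each of 15312 genes.

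The scripts were tested on simulated data, in which the deposited values were shuffled between genes and known differences were added to 200 of 18014 genes. At 2 h, 88% of genes given a log2 difference of 1.5 and 97% of those given 3 were recovered at 2-fold. At 6 h these were 91% and 100%, at 1 day 93% and 100%, and at 14 days 92% and 100%. Genes without an added difference past 2-fold numbered 2153, 1310, 716 and 725 from 2 h to 14 days, since shuffled values keep the spread of each array. In the first run, 1 list per array had no added difference, and these had percentiles of 0.21, 88.1, 58.6 and 20.6, the first outside the central 99%. Of 200 further lists with no added difference, 2 fell outside the central 99%. The shuffling removes any correlation between the genes of a list, so these runs do not cover it. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.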

Results

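Gene expression was measured in the substantia nigra pars compacta of 5 male common marmosets after MPTP or vehicle. This midbrain nucleus holds the dopamine neurons that are lost in Parkinson's disease. MPTP is a neurotoxin whose metabolite is taken up by dopamine neurons and blocks complex I of the mitochondrial respiratory chain. 1 animal received vehicle, and 4 received a single intravenous dose of 2.5 mg/kg MPTP and were killed 2 or 6 h, or 1 or 14 days, after the dose. RNA of the nucleus, cut out by laser microdissection, was amplified in 2 rounds and hybridised to 1 human 2-colour oligonucleotide array per time point. Each array set 1 MPTP animal (Cy5) against the same vehicle animal (Cy3), with no dye swap. The comparisons ask how expression stood against vehicle at each time and how it differed between times.

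Values are log2 ratios of MPTP over vehicle for RNA, and a protein or subunit named below stands for its transcript. Scale and direction are not stated in the table and were read from the form of the values and the dyes in the labels. If the ratio had been formed the other way, every sign below would turn. No time point had a replicate, so no difference was tested against the spread between animals, and no p-values across genes are given. An SD beside a gene is taken over its array features, and a 95% interval beside a gene list is a bootstrap interval over its members. The 4 arrays held values for 43931 features, of which 29033 carried 1 gene symbol, for 18014 genes. The SD of the gene log2 ratios was 0.71 at 2 h, 0.57 at 6 h, 0.48 at 1 day and 0.47 at 14 days.

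With the ratio read in this direction, the listed markers of dopamine neurons were not lower than in the vehicle animal as a group at any time. With 1 vehicle sample and 1 animal per time, this does not show whether dopamine neurons were spared. None of the 21 markers with a readable ratio was at least 2-fold lower on any array. If the signs turned, LMX1B, SNCG, ALDH1A1 and KCNJ6 would be at least 2-fold lower at times given below. TH, the rate-limiting enzyme of dopamine synthesis, lay at 0.90 ± 0.52 (SD, 2 features) at 2 h, 0.64 ± 0.62 at 6 h, 0.39 ± 0.68 at 1 day and 0.50 ± 0.59 at 14 days. ALDH1A1, an aldehyde dehydrogenase of ventral-tier dopamine neurons, lay at 0.35 at 2 h, 1.06 at 6 h, 1.23 at 1 day and 0.09 at 14 days. KCNJ6, the potassium channel subunit GIRK2, was higher by 1.01 at 1 day, and at 2 h LMX1B, a midbrain transcription factor, was higher by 1.76 and SNCG, gamma-synuclein, by 1.06. The vesicular monoamine transporter SLC18A2 lay at 0.22, 0.27 and 0.17 from 6 h to 14 days. DDC, which converts L-DOPA to dopamine, lay at −0.76 at 2 h and at 0.67, 0.46 and 0.31 later. The dopamine transporter SLC6A3 had 1 feature, listed as exactly 0 on all 4 arrays, so no ratio can be read from it. NR4A2, a transcription factor of dopamine neurons, lay at −0.32, 0.24, 0.21 and 0.06. The median of the list was 0.22 at 2 h, 0.22 at 6 h, 0.21 at 1 day (95% interval −0.014 to 0.36) and 0.09 at 14 days. Only the 1 day value lay outside the central 99% of 10000 random lists (percentile 99.6), and it lay inside with the mean over features (0.20, percentile 99.3). With only the 4 members that have 2 or more features, it was 0.28 (percentile 97.8).

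Markers of other cells differed from vehicle in the same samples. Erythrocyte markers were higher, with medians over 8 genes of 0.73 at 2 h (95% interval 0.39 to 1.19), 0.33 at 6 h, 0.49 at 1 day and 0.81 at 14 days (0.37 to 1.07). All 8 lay above 0 at 2 h, 1 day and 14 days. The alpha-globin gene HBA1 lay at 2.66 at 2 h and 1.12 at 14 days, and ALAS2, the erythroid enzyme of haem synthesis, at 1.07 ± 0.31 (2 features) at 14 days. Markers of GABAergic neurons had medians over 6 genes of −0.17 at 2 h (95% interval −1.57 to 0.35), −0.79 at 6 h (−1.17 to 0.09), −0.40 at 1 day (−0.90 to 0.0016) and −0.66 at 14 days (−1.39 to −0.34), so only the last interval excluded 0. GAD2, a glutamate decarboxylase that makes GABA, lay at −2.18, −1.30, −0.96 and −1.83, and the neuropeptide gene SST at −1.05 at 6 h. The erythrocyte list lay outside the central 99% of random lists at 2 h, 1 day and 14 days, and the GABAergic list at 6 h and 14 days. After subtraction of a regional median along the gene order, the 5 erythrocyte markers left had medians of 0.38, 0.24 and 0.28 at 2 h, 1 day and 14 days, inside the central 99%.

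Vascular markers had medians of 0.09, 0.30, 0.23 and 0.34 over 14 genes, the last outside the central 99% (percentile 99.9). PDGFRB, a receptor of pericytes, lay at 1.80 at 6 h, 1.12 at 1 day and 1.03 at 14 days. Astrocyte markers had medians of −0.38, −0.16, 0.0058 and 0.07 over 12 genes. At 2 h the calcium-binding protein S100B lay at −1.60, the intermediate filament VIM at −1.51 ± 0.61 (2 features) and the gap junction protein GJA1 at −1.34 ± 0.48 (2 features). GFAP, the astrocyte filament that marks reactive gliosis, lay at −0.53, −0.37, −0.92 and −0.84, with an SD of 1.30 between its 2 features at 1 day. 1 of the 2 was listed as exactly 0 on all 4 arrays, and the other lay at −0.73, −1.84 and −1.69 from 6 h to 14 days. Microglial markers had medians of 0.00056, 0.12, 0.011 and 0.14 over 17 genes, with TYROBP, a signalling adaptor of microglia, at 2.01 and the transcription factor SPI1 at −1.73 at 2 h, and the complement gene C1QC at 1.58 at 14 days. Oligodendrocyte markers had medians of −0.12, 0.06, 0.0090 and 0.09 over 14 genes. At 6 h the oligodendrocyte genes ERMN (−1.60 ± 0.04, 2 features) and MBP (−1.57 ± 0.94, 2 features) were lower. Markers of other midbrain neurons had medians of 0.03, 0.08, 0.05 and −0.08 over 10 genes, and general neuronal markers 0.15, 0.08, 0.02 and −0.07 over 18 genes.

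**Figure D1:**
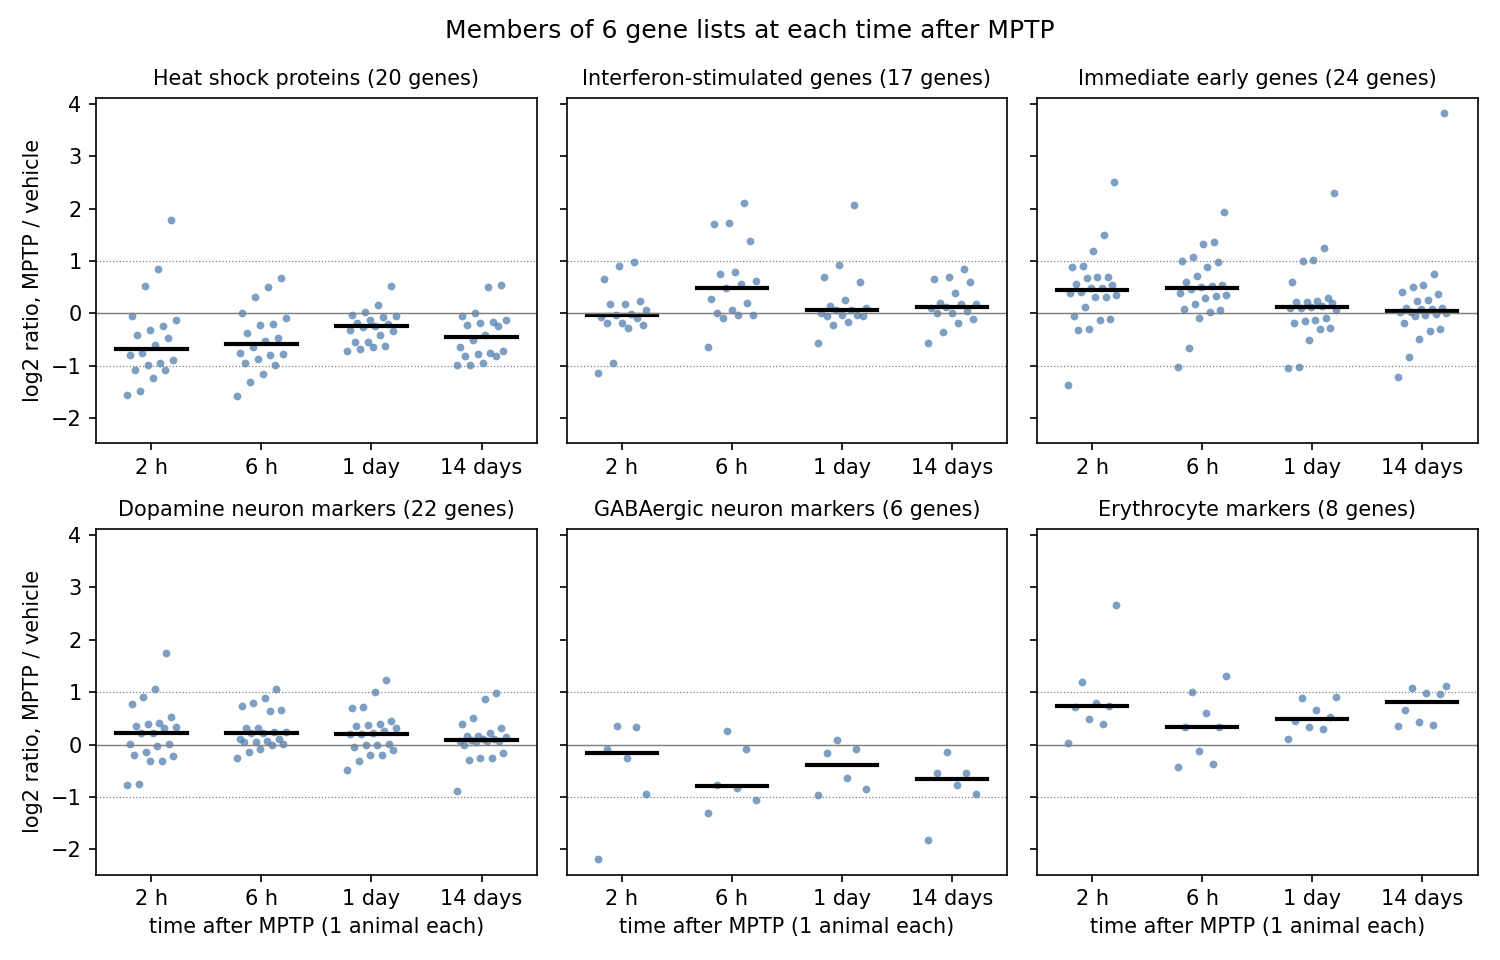
Log2 ratios of MPTP over vehicle (vertical axis) for every measured member of 6 gene lists at the 4 times after MPTP (horizontal axis, 1 animal each). Points are genes, black bars are list medians and dotted lines mark 2-fold differences. The heat shock medians lie below 0 at all 4 times (−0.69, −0.58, −0.25 and −0.46), and the interferon median is 0.48 at 6 h.

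At 2 h after MPTP, transcripts of heat shock proteins were lower than in the vehicle animal, and immediate early genes were higher. Heat shock proteins are chaperones that refold damaged proteins, and immediate early genes respond within minutes to neuronal activity or stress. The heat shock list had a median of −0.69 over 20 genes (95% interval −0.97 to −0.28), with 5 members at least 2-fold lower and 1 higher. The co-chaperone DNAJB1 lay at −1.56, HSPH1 of the Hsp110 family at −1.49 and the co-chaperone DNAJA1 at −1.25 ± 0.40 (2 features), while HSF1, the transcription factor that drives heat shock genes, lay at 1.78. The immediate early list had a median of 0.44 over 24 genes (0.25 to 0.66), led by the nuclear receptor NR4A1 at 2.51, FOS (2.83-fold higher) and EGR4 at 1.18. JUN, the partner of FOS in the transcription factor AP-1, lay at −1.37. Ribosomal proteins had a median of −0.38 over 57 genes (−0.63 to 0.086) and went both ways, with RPS14 at −1.41 ± 0.46 (4 features) and RPLP1 at −1.33 ± 0.15 (2 features) against RPS15 at 2.03 ± 0.23 (2 features) and RPL36 at 1.63. These 3 lists lay outside the central 99% of random lists, as did the erythrocyte markers. The immediate early list at 2 h lay inside with only its 10 members that have 2 or more features (0.38) and after subtraction of a regional median (0.25, percentile 97.9).

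Subunits of the respiratory chain went both ways at 2 h. Of 36 complex I genes, 5 were at least 2-fold higher and 4 lower, with a list median of −0.16 (95% interval −0.51 to 0.40). NDUFS8, a core subunit, lay at 2.41, NDUFV3 at 1.72 ± 0.94 (3 features), NDUFA3 at 1.59 and NDUFS7 at 1.33 ± 0.24 (2 features), while NDUFB5 lay at −1.04. Of 33 genes of complexes III and IV and ATP synthase, 3 were at least 2-fold higher and 2 lower. ATP5F1B lay at 1.52, ATP5MF at 1.22 ± 0.27 (2 features) and UQCRC1 at 1.21, against UQCRB of complex III at −1.27. BDNF, a growth factor that sustains dopamine neurons, lay at 1.05 ± 0.56 (2 features) and NRTN, neurturin, at 1.15, in a neurotrophic list with a median of 0.35 over 12 genes (percentile 98.8, inside the central 99%). Of the genes linked to inherited parkinsonism, FBXO7 lay at −1.24 and PARK7, or DJ-1, at −1.03. The death receptor gene TNFRSF10B lay at 2.86 ± 3.53 (2 features).

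In all, 985 genes (5.47%) were at least 2-fold higher at 2 h and 1301 (7.22%) at least 2-fold lower. With the arrays scaled to 1 median absolute deviation these were 400 and 511, fewer than the 781 and 620 at 1 day, so the order of the times by number of genes is not settled. Among the 7411 genes with 2 or more features, all features were at least 2-fold higher for 37 and lower for 99. Shuffling the features 1000 times gave a mean of 24.3 (highest 41) and 52.2 (highest 74). Repeat spots of 1 probe could not be told from different probes, and would raise the observed counts above the shuffles. The lower genes with agreeing features included TTC12, a dynein arm assembly factor (−3.24 ± 0.24, 2 features), RSRP1 (−2.67 ± 0.21, 2 features), the translational regulator CPEB3 (−2.44 ± 0.07, 2 features), RPAP3, a cofactor of Hsp90 (−2.27 ± 0.07, 10 features), and BNIP3L, a receptor for the removal of mitochondria (−2.03 ± 0.50, 2 features). Among the higher ones were TRAPPC5 of the vesicle-tethering TRAPP complex (2.04 ± 0.07), TRMT112 (1.94 ± 0.59) and the glycolytic enzyme ALDOA (1.73 ± 0.74), each with 2 features. VWA1 (3.23 ± 2.73) and NEK2 (3.22 ± 2.69), each with 2 features, lay above these. ABL2, a tyrosine kinase, had the highest median (4.02 ± 3.69, 2 features), with 1 feature at the limit of the deposited scale. The most extreme genes had 1 feature each, with IFNA6 and SLURP1 both at 6.62, also at that limit, and S100A3 at −5.97.

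At 6 h, genes induced by interferon, immediate early genes and metallothioneins were higher than in the vehicle animal, and heat shock genes were lower. The interferon list had a median of 0.48 over 17 genes (95% interval −0.0044 to 0.79, percentile 100), and 4 members were at least 2-fold higher. These were the antiviral genes RSAD2 (2.10 ± 2.34, 2 features), IFI6 (1.72 ± 0.16, 2 features), ISG15 (1.70) and MX1 (1.37). The immediate early list had a median of 0.48 over 24 genes (0.29 to 0.78), with IER2 at 1.94 ± 0.33 (2 features), NR4A1 at 1.36, FOS at 1.32 and the transcription factor EGR1 at 1.07. Metallothioneins, small proteins that bind zinc and copper, had a median of 0.52 over 9 genes (−0.017 to 0.75, percentile 99.8), with no member past 2-fold. After subtraction of a regional median, which left 2 metallothioneins, it was 0.36 (percentile 89.9). The heat shock list had a median of −0.58 (−0.83 to −0.22), with 3 of 20 members at least 2-fold lower: BAG3, a co-chaperone of selective autophagy (−1.57 ± 0.83, 2 features), HSP90AB1 (−1.32 ± 0.43, 3 features) and HSPH1 (−1.15).

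The cytokine genes CCL2 and IL6 lay at 1.22 and 1.21 at 6 h, in an inflammation list with a median of 0.22 over 20 genes (0.11 to 0.31, percentile 95.3, inside the central 99%). CEBPD, a transcription factor of the acute phase response, lay at 1.90, and EGLN3, a hypoxia-induced prolyl hydroxylase, at 1.23. GFRA1, the receptor for GDNF, lay at −1.60 ± 2.34 (2 features). Of the proteasome subunits, PSMC6 (−1.43 ± 0.18, 4 features), PSMA2 (−1.15), PSMA3 (−1.15) and PSMC2 (−1.04) were at least 2-fold lower, with a list median of −0.12 over 34 genes.

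In all, 607 genes (3.37%) were at least 2-fold higher at 6 h and 700 (3.89%) lower. All features were at least 2-fold higher for 18 genes and lower for 39, against shuffled means of 10.2 (highest 20) and 18.9 (highest 34). Repeat spots may again raise the observed counts. After IER2, the higher ones included CKB, brain creatine kinase (1.74 ± 0.21), the complex I subunit NDUFS7 (1.66 ± 0.36), P2RX7, an ATP-gated channel (1.66 ± 0.62), and the ATP synthase subunit ATP5F1D (1.43 ± 0.02), each with 2 features. Among the lower ones were TTC12 (−2.68 ± 0.36), SPART, or spartin (−1.84 ± 0.18), RSRP1 (−1.83 ± 1.04) and FBXO33 (−1.66 ± 0.09), each with 2 features. IZUMO1 (6.64) and FAHD1 (−6.64) had the most extreme values, from 1 feature each and at the limits of the deposited scale.

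At 1 day, subunits of respiratory complexes III and IV and of ATP synthase were slightly higher as a group, and heat shock genes were still lower. The respiratory list had a median of 0.18 over 33 genes (95% interval 0.11 to 0.38, percentile 99.7), with 24 above 0 and UQCRQ, a complex III subunit, at 1.09 ± 0.39 (2 features). With only the 13 members that have 2 or more features, the median was 0.18 and its percentile 96.9, inside the central 99%. Complex I genes had a median of 0.12 over 36 genes (percentile 96.8), with 29 above 0. The heat shock median was −0.25 (−0.49 to −0.10), with 17 of 20 below 0 and none past 2-fold. FOS lay at 1.25 and EGR3 at 2.29, while JUN lay at −1.05 and EGR1 at −1.02, in an immediate early list with a median of 0.11 (percentile 93.6). GSTP1, a glutathione transferase, lay at 1.86 and RSAD2 at 2.07 ± 3.14 (2 features).

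In all, 409 genes (2.27%) were at least 2-fold higher at 1 day and 301 (1.67%) lower. All features passed for 7 genes higher and 7 lower, against shuffled means of 5.62 (highest 18) and 3.14 (highest 10). The higher ones were led by LILRA5 (3.17 ± 2.37), PPIL6 (2.62 ± 2.17) and SMU1 (1.96 ± 0.68), each with 2 features. They also included the splicing factor CWC25 (1.29 ± 0.14), APOC1, an apolipoprotein (1.17 ± 0.20), and TST, a mitochondrial sulphur transferase (1.07 ± 0.05), each with 2 features. The lower ones included TTC12 (−2.47 ± 0.46), INHBA, the activin A subunit (−1.57 ± 0.71), and SNTB1, a syntrophin (−1.19 ± 0.11), each with 2 features. AVP, the vasopressin gene, had the highest value (5.88) and FAM184B the lowest (−4.19), from 1 feature each.

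At 14 days, heat shock genes, proteasome subunits and GABAergic markers were lower than in the vehicle animal, and erythrocyte and vascular markers were higher. Median differences between 14 days and 1 day were 0.15, −0.38 and −0.0067 for erythrocyte, GABAergic and vascular markers. Neither these nor their differences from 2 h and 6 h lay outside the central 99% of random lists. With the arrays scaled to 1 spread, the GABAergic (−0.60) and vascular (0.35) differences from 2 h did. For these markers the shared vehicle sample therefore cannot be told apart from MPTP. The heat shock median was −0.46 over 20 genes (95% interval −0.77 to −0.18), with 17 below 0 and none past 2-fold. Proteasome subunits had a median of −0.17 over 34 genes (−0.31 to −0.075, percentile 0.25), with 26 below 0. PSMC6 lay at −1.13 ± 0.08 (4 features), against PSMC4 at 1.44. With only members that have 2 or more features, the proteasome median was −0.19 over 13 genes (percentile 2.75) and the vascular median 0.23 over 7 genes (percentile 95.5), both inside the central 99%. The endothelial receptor TIE1 lay at 3.85. GSTP1 lay at 2.28, the anti-apoptotic gene BCL2L1 at 2.08 ± 3.16 (2 features), hexokinase HK1 at 1.58 ± 2.93 (2 features) and the chemokine CXCL8 at −1.53. HMOX1, the haem oxygenase induced by oxidative stress, lay at −0.77, and at −0.75, −0.65 and −0.58 on the earlier arrays. MAOB, which turns MPTP into its toxic metabolite, lay at −0.0054, after 0.0074, 0.18 and −0.07.

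In all, 390 genes (2.16%) were at least 2-fold higher at 14 days and 382 (2.12%) lower. All features passed for 3 genes higher and 9 lower, against shuffled means of 5.14 (highest 14) and 5.12 (highest 17). The higher ones were the endocytic sorting nexin SNX18 (1.42 ± 0.06), SWAP70 (1.42 ± 0.24) and APOC1 (1.13 ± 0.04), and the lower ones included TTC12 (−2.79 ± 0.73), INHBA (−1.66 ± 0.43), CPEB3 (−1.26 ± 0.19) and PARP4 (−1.15 ± 0.03), each with 2 features. The highest values, JADE1 (6.28) and LRRC41 (6.01), and the lowest, MYH13 (−4.22), came from 1 feature each.

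**Figure D2:**
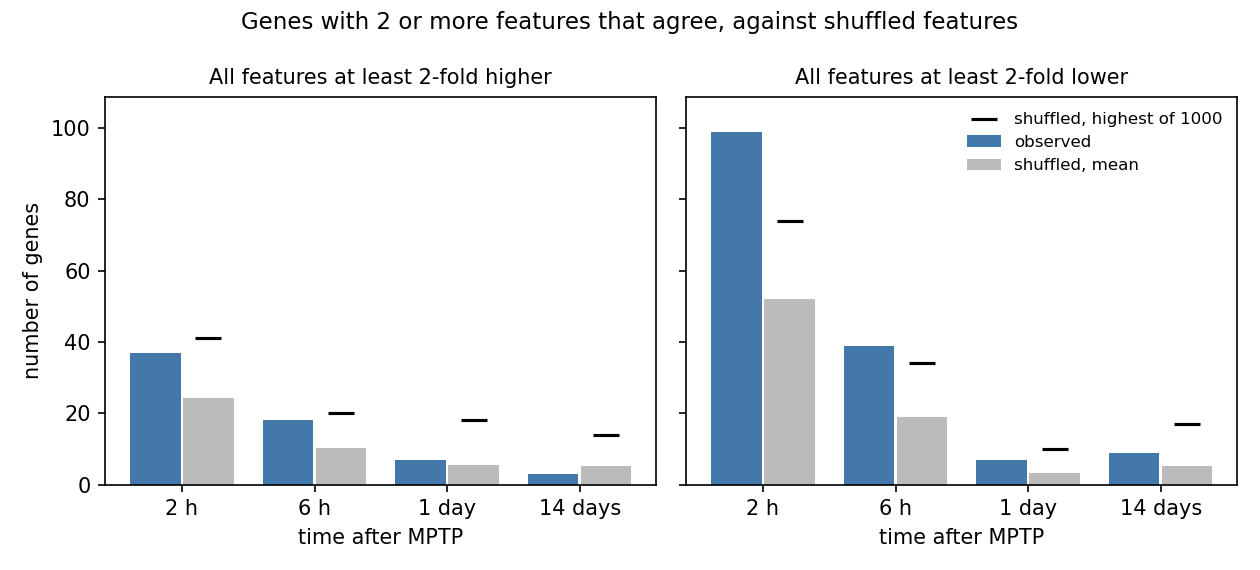
Number of genes (vertical axis) whose 2 or more features were all at least 2-fold higher (left) or lower (right) at each time after MPTP (horizontal axis). Blue bars are observed counts, grey bars the mean of 1000 shuffles of the features and black dashes the highest shuffle. Observed counts of lower genes at 2 h (99) and 6 h (39) lie above the highest shuffle, and the other 6 do not.

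Over the time course, 27 genes were at least 2-fold higher on all 4 arrays and 39 lower. The higher ones were led by KCNS1, a potassium channel subunit (1.57, 4.55, 5.41 and 4.48), HES5, a target of Notch signalling (2.11, 1.46, 1.77 and 2.23), and ORC1 of the origin recognition complex (1.74, 1.33, 1.35 and 1.95). The lower ones were led by TTC12, GADD45A, a growth arrest and DNA damage gene (−2.38, −2.82, −2.73 and −3.24), the potassium channel regulator KCTD8 (−1.77, −1.77, −2.88 and −1.81), and CALB1, the calcium buffer calbindin (−2.19, −1.68, −1.90 and −1.79). GRP, gastrin-releasing peptide, lay at −1.88, −1.68, −1.68 and −1.43. Of these 66 genes, only TTC12 had 2 or more features that all passed on every array. All 4 arrays share the vehicle animal, and simulated unchanged samples against 1 shared control gave a mean of 117 genes higher and 112 lower on all 4. The simulated arrays were wider than the real ones at 1 day and 14 days, which raises these counts, so no shortfall is read from them. Counts on the other 3 arrays were 49 and 88 without the 1 day array, 65 and 67 without the 14 days array, 43 and 53 without the 6 h array, and 40 and 49 without the 2 h array.

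An early difference, at least 2-fold in 1 direction at both 2 h and 6 h and within 0.5 at 1 day and 14 days, was found for 81 genes, 32 higher and 49 lower. Among them were the integrin ITGA3 (4.16 and 3.52), the RNA polymerase subunit POLR2J (2.19 and 1.90), NR4A1 and MCM3, a replication helicase subunit (2.12 and 1.46). A late difference, at least 2-fold at 14 days and within 0.5 before, was found for 116 genes, 62 higher and 54 lower. JADE1, GAS2L1 (5.95), TRIML1 (−2.67) and the volume-regulated channel subunit LRRC8C (−2.58) led them, each with 1 feature. ITGA3 was listed as exactly 0 at 1 day and 14 days, and TRIML1 at 2 h, 6 h and 1 day. Early and late genes numbered 11 and 188 with the arrays scaled to 1 median absolute deviation, 3 and 28 at 3-fold, and 4 and 0 where 2 or more features all had to pass. With exact zeros taken as not measured they numbered 72 and 104.

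The vehicle animal cancels in differences between arrays if the arrays read ratios on the same scale. Where the arrays are scaled to 1 spread, each by its own factor, it no longer cancels fully. Interferon genes were higher at 6 h than at 2 h by a median of 0.37 over 17 genes (95% interval 0.089 to 0.77). The differences from 6 h to 1 day (−0.14, −0.53 to −0.030) and to 14 days (−0.14, −1.03 to 0.0028) lay inside the central 99% of random lists. Metallothioneins lay lower at 1 day than at 6 h, by a median difference of −0.87 over 9 genes (−1.32 to 3.0e-05), and at 14 days than at 6 h (−1.01, −1.24 to 0.16). Immediate early genes lay lower at 1 day than at 6 h (−0.32, −0.60 to −0.017) and at 14 days than at 6 h (−0.38, −0.72 to −0.096). Heat shock genes were higher at 1 day than at 6 h by 0.33 (0.045 to 0.56), but by 0.23 (−0.061 to 0.46) and inside the central 99% with the arrays scaled to 1 spread. Proteasome subunits lay lower at 14 days than at 1 day (−0.23, −0.34 to −0.15), and ribosomal proteins were higher at 1 day than at 2 h by 0.44 (0.12 to 0.54). Glucocorticoid-induced genes were higher at 6 h than at 2 h by 0.54 over 13 genes (0.077 to 0.92), and inflammation genes lay lower at 1 day than at 6 h (−0.37, −0.52 to −0.12). Neurotrophic genes lay lower at 6 h than at 2 h (−0.43, −0.86 to −0.055), as did erythrocyte markers (−0.50, −1.10 to −0.15). With the arrays scaled to 1 spread, the erythrocyte difference was −0.32 (−0.65 to 0.14), inside the central 99%. Microglial markers were higher at 14 days than at 1 day by 0.25 (0.021 to 0.39). General neuronal markers lay lower at 14 days than at 1 day (−0.28, −0.36 to 0.053), as did complexes III and IV and ATP synthase (−0.20, −0.38 to −0.042). Apart from the 2 interferon differences from 6 h to later times, these are among the 22 of 174 list differences between 2 arrays that lay outside the central 99% of random lists, of which 17 still did with the arrays scaled to 1 spread.

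Of single genes, 1600 differed by at least 2-fold between 2 h and 6 h, 883 higher and 717 lower at 6 h. Between 6 h and 1 day 1131 genes differed (646 higher, 485 lower), and between 1 day and 14 days 864 (408 higher, 456 lower). With the arrays scaled to 1 median absolute deviation, 1029 differed between 2 h and 6 h and 1423 between 1 day and 14 days, so this falling order depends on the spread of the arrays. Across genes, which are not independent replicates, Pearson's r between arrays was 0.48 for 2 h and 6 h (Spearman's rho 0.53), 0.40 for 2 h and 1 day (0.44), 0.44 for 2 h and 14 days (0.51), 0.40 for 6 h and 1 day (0.46), 0.44 for 6 h and 14 days (0.50) and 0.41 for 1 day and 14 days (0.48). Simulated unchanged samples with 1 shared control gave r of 0.44, 0.48, 0.48, 0.54, 0.54 and 0.59. The covariance was 0.195 for 2 h and 6 h against 0.160 simulated, and lay between 0.0932 and 0.146 for the other 5 pairs, below the simulated 0.159 to 0.160. For 2 h and 6 h, 204 genes were at least 2-fold higher on both arrays and 328 lower, against 33.2 and 50.6 for independent lists and means of 217 (highest 255) and 198 (highest 234) in the simulations. For 1 day and 14 days these were 79 and 81, against 8.85 and 6.38 for independent lists and simulated means of 204 and 180. Simulated arrays were narrower than the real one at 2 h and wider at 1 day and 14 days. No excess or shortfall is therefore read from these overlaps or from r.

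The remaining gene groups lay inside the central 99% of random lists at every time, or did so outside the times already given. From 2 h to 14 days, medians for monoamine metabolism were 0.0074, 0.08, 0.05 and 0.07 over 9 genes, with PTS, an enzyme of tetrahydrobiopterin synthesis, at −2.51 at 2 h and −1.53 at 14 days. Genes of inherited parkinsonism had medians of −0.15, −0.11, −0.04 and −0.09 over 15 genes, and complex I −0.16, 0.0055, 0.12 and 0.05. Complexes III and IV and ATP synthase had −0.18, 0.016 and 0.08 at 2 h, 6 h and 14 days. The unfolded protein response had −0.09, −0.014, 0.017 and −0.09 over 24 genes, with PDIA6, a disulphide isomerase, at 2.04 at 2 h and EIF2AK3, the stress kinase PERK, at −1.52 at 2 h and −1.33 at 14 days. Antioxidant genes had −0.09, −0.02, 0.08 and −0.15 over 25 genes, with NFE2L2, the regulator NRF2, at −1.11 ± 1.89 (2 features) at 2 h. Apoptosis genes had 0.18, 0.14, 0.04 and 0.03 over 23 genes. Metallothioneins lay at −0.0097, −0.28 and −0.25 at 2 h, 1 day and 14 days, and the proteasome at −0.22 and 0.02 at 2 h and 1 day.

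Inflammation genes had medians of 0.10, −0.04 and 0.04 at 2 h, 1 day and 14 days, interferon genes −0.03, 0.06 and 0.13, and immediate early genes 0.05 at 14 days. Hypoxia and glycolysis genes had −0.14, 0.24, 0.04 and 0.03 over 18 genes, with GAPDH, a glycolytic enzyme, at 1.93 at 2 h. Glucocorticoid-induced genes had −0.34, 0.08, −0.04 and 0.00017 over 13 genes, with the transcription factor KLF9 at −1.95 at 2 h. Neurotrophic genes had −0.11, −0.13 and 0.05 from 6 h to 14 days. Iron genes had −0.36, −0.06, −0.0061 and 0.0067 over 9 genes, with CP, the copper ferroxidase ceruloplasmin, at −1.33, −1.15 and −1.79 from 6 h to 14 days. Cell cycle genes had 0.09, −0.04, 0.07 and −0.08 over 16 genes, ribosomal proteins −0.08, 0.0027 and 0.05 after 2 h, and reference genes 0.08, −0.04, 0.06 and −0.19 over 8 genes. Of 116 list medians, 18 lay outside the central 99% of random lists. The 1.16 expected by chance assumes that members of a list vary together no more than random genes do, which was not tested. All arrays also share the vehicle animal, so the medians of a list at different times are not independent. No effect of MPTP is therefore read from this count.

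Agreement between features limits how far a single gene can be read. The 2 features of 1 accession had a Pearson's r, across 4418 pairs, of 0.114 at 2 h, 0.173 at 6 h, 0.0431 at 1 day and 0.0936 at 14 days. Where a gene had a feature at least 10-fold from vehicle on an array, its other features there lay at a median of 0.0020 in that direction (95% interval −0.0099 to 0.061). This median was over 466 values from the 4 arrays together, so a feature can enter more than once. Over 71 accessions with 10 or more features, the median SD between features was 0.23, 0.21, 0.18 and 0.24.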

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

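The tests in this part were chosen after the results were seen, except the subtraction of a regional trend from the heat shock list, whose bound was written before its result was seen. 5 genes of the fixed lists lay at least 2-fold higher at one time and at least 2-fold lower at another. With 1 animal per time and 1 feature per gene, none of these differences was tested. TOP2A, the DNA topoisomerase of dividing cells, lay at 4.50 at 2 h and −3.36 at 14 days, a difference of 7.85. TIE1 lay at 3.85 at 14 days and −1.12 at 6 h, a difference of 4.97. SLC18A3, the vesicular acetylcholine transporter, lay at 1.57 at 1 day and −1.76 at 14 days, a difference of 3.33. The activity-regulated gene ARC lay at 1.02 at 1 day and −1.23 at 14 days, a difference of 2.25. EGR1 lay at 1.07 at 6 h and −1.02 at 1 day, a difference of 2.09.

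Among the 14801 unnamed features, which enter no gene value, 526 (3.55%) were at least 2-fold lower on all 4 arrays and 29 higher. Of the named features 95 (0.327%) were lower on all 4. Medians of the 526 were −3.61, −3.42, −2.02 and −3.82 from 2 h to 14 days. Of their consecutive feature numbers, 85.7% were exactly 7 apart, against 3.08% of all unnamed features. An annotation of control spots was not used here, so whether these are control spots stays open.

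Heat shock genes were lower on all 4 arrays. Subtracting a regional trend along the genome, as estimated here, left the list lower at 6 h. After the subtraction the median at 6 h was −0.44 (95% interval −0.93 to −0.19, 19 genes), against −0.58 over 20 genes before. The estimated trend had an SD of 0.14 across genes at 6 h, so its subtraction could move the median little and the outcome was close to fixed. It does not decide whether a regional cause that the estimate misses plays a part. The vehicle animal's sample, shared by all 4 arrays, stays open: 2 of the 6 differences between arrays had intervals that excluded 0, the largest being 0.33 for 1 day minus 6 h (0.045 to 0.56), but with the arrays scaled to 1 spread it was 0.23 (−0.061 to 0.46). The other, 14 days minus 1 day, was −0.13 (−0.24 to −0.027) and, scaled, −0.13 (−0.23 to −0.013), but lay inside the central 99% of random lists both ways (percentiles 4.93 and 8.78). High heat shock transcripts in the vehicle animal could therefore account for much of the pattern, and cannot be told apart from an effect of MPTP with 1 vehicle animal.

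Interferon-stimulated genes were higher at 6 h. The vehicle animal's sample, shared by all 4 arrays, stays open, since 1 day minus 6 h had a median of −0.14 over 17 genes (95% interval −0.53 to −0.030), or −0.13 (−0.45 to 0.078) with the arrays scaled to 1 spread, and 14 days minus 6 h was −0.14 (−1.03 to 0.0028). Of the 3 differences with another array, only 6 h minus 2 h, at 0.37 (0.089 to 0.77) and, scaled, 0.33 (0.037 to 0.98), lay outside the central 99% of random lists, and it was picked out because 6 h was highest. The state of the animal taken at 6 h, such as an infection, also stays open, since 1 animal was taken then. An interferon response to MPTP at 6 h may be followed up as a hypothesis only with further animals.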

How the results depend on the processing

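The regional subtraction, the exclusion of exact zeros, the centring on named features and the arrays left out of the counts over 4 arrays were chosen after the data were seen. No paired analysis was possible because each time point had 1 array and 1 animal. A filter on dim features was planned and not run, since the table holds no intensities, and signal over background stays unknown. No list median outside the central 99% changed sign, and 58 of the 782 recomputed for lists inside it did. The largest of the 58 was 0.11 in size beforehand, and the largest afterwards was 0.23. Scaling the arrays cannot change a sign. Of 924 list medians recomputed under the alternatives, 892 moved by less than 1 bootstrap SD and 32 by more. The 924 include 116 from the filter on missing values, which could not move. They also include 116 without centring and 116 centred on named features, where an array shifts by 1 small constant. These cases say little about how firm the medians are. The number of lists outside the central 99%, 18 of 116, lay between 14 and 19. The correlations between arrays moved by less than 0.1. Values without centring, the mean over features, exact zeros taken as not measured and centring on named features moved no count by over 1.5 times, and the filter on missing values removed no gene.

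With a 3-fold threshold, 274 genes were higher and 343 lower at 2 h, 156 and 165 at 6 h, 114 and 81 at 1 day, and 87 and 76 at 14 days. On all 4 arrays 0 were higher and 5 lower, 3 genes had an early and 28 a late difference, and 545, 358 and 294 differed between consecutive times. These follow from the stricter threshold. With the arrays scaled to 1 median absolute deviation, counts at 2 h were 400 higher and 511 lower, at 1 day 781 and 620, and at 14 days 642 and 676, so the order of the times by number of genes depends on the spread of each array. Early genes were then 11 and late genes 188, and 1029 genes differed between 2 h and 6 h and 1423 between 1 day and 14 days. List medians moved to 0.31 for immediate early genes at 2 h, −0.48 for heat shock genes at 2 h, and 0.52 and 0.65 for erythrocyte markers at 2 h and 1 day.

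With only genes whose 2 or more features all passed, 37 were higher and 99 lower at 2 h, 18 and 39 at 6 h, 7 and 7 at 1 day, and 3 and 9 at 14 days. On all 4 arrays 0 were higher and 1 lower, 4 genes had an early and 0 a late difference, and 380, 276 and 175 differed between consecutive times. Fewer genes could pass, since 7411 have 2 or more features. Among members with 2 or more features, the heat shock median was −0.47 at 2 h, −0.78 at 6 h and −0.76 at 14 days. Dopamine neuron markers and complexes III to V at 1 day, immediate early genes at 2 h, and proteasome and vascular genes at 14 days then lay inside the central 99%, and GABAergic markers had too few members for a value. Apoptosis genes at 2 h (0.35) and metallothioneins at 1 day (−0.42) and 14 days (−0.47) then lay outside. Dopamine neuron markers at 1 day also lay inside with the mean over features (0.20) and without exact zeros (0.19), as did complexes III to V without exact zeros (0.16). GABAergic markers at 1 day lay outside with the mean over features (−0.59).

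After subtraction of the regional median, medians were 0.25 and 0.31 for immediate early genes at 2 h and 6 h, 0.36 for metallothioneins at 6 h, and 0.38, 0.24 and 0.28 for erythrocyte markers at 2 h, 1 day and 14 days. Immediate early genes at 2 h, metallothioneins at 6 h and the erythrocyte markers then lay inside the central 99% of random lists. Dopamine neuron markers at 6 h (0.29, percentile 99.7) and neurotrophic genes at 2 h (0.51) then lay outside. Only 2 metallothioneins and 5 erythrocyte markers had a place in the gene order, so fewer members entered, and the share of this in the shift was not tested. With 1 array left out, 40 to 65 genes were higher and 49 to 88 lower on the other 3 arrays. Without the 6 h array 43 were higher, without the 1 day array 49 higher and 88 lower, and without the 14 days array 65 higher and 67 lower, as fewer arrays had to pass.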

Other observations

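All tests in this part were chosen after the results were seen. Genes that lie close together in the marmoset genome had weakly correlated ratios, most at 2 h and 6 h. Over 15319 genes in the order of the RefSeq table, Pearson's r between a gene and the next was 0.122 at 2 h, 0.112 at 6 h, 0.0254 at 1 day and 0.0474 at 14 days, where the highest of 100 shuffled orders gave 0.0154, 0.0229, 0.0175 and 0.0152. Duplicated or jointly regulated genes directly side by side are argued against as the whole cause at 2 h. There r between genes 10 places apart was still 0.082, above the highest shuffled value of 0.0264. At 6 h and 14 days it was 0.0746 and 0.0414, also above the highest shuffled values (0.0245 and 0.0171), and at 1 day 0.0068, below it (0.0175). Longer runs of such genes stay open, since they can span 10 places or more and were not removed. Base composition, which runs in long regions along the genome and can act on amplification and hybridisation, may be the source of this trend, but stays open: 0 genes had a GC content in the tables used. No other biological explanation was tested.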
